A study of Arabidopsis thaliana with 6 samples.

How the data were processed

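RNA was measured in roots of Arabidopsis thaliana on 6 one-colour NimbleGen expression arrays, 3 for dark-grown and 3 for light-grown roots. Per the labels, plants grew for 12 days on diluted Murashige and Skoog agar, with the shoots of both groups in white light of 75 µmol per square metre per second and the roots either lit, which the labels call the control, or kept dark. The labels describe the replicates as separate plates. RNA was extracted with Trizol, cleaned on columns, copied into double-stranded cDNA and labelled with Cy3.

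The deposited values are log2 expression values for 37118 transcript models of 32627 loci. The sorted values of the 6 arrays were equal within 0.01, so the values had been quantile normalized before deposit, and they were used here without a further transformation or scaling. The submitters' processing notes name limma, with no version. Background correction, the summary of probes into transcript models, and the annotation release of the array are not given in the sources used here. The table holds no detection calls and no probe values. Levels of different probes are not comparable, so only differences between groups are compared between genes. Array measurements have no read depth. Their number, 3 per group, limits the precision.

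Symbols came from the TAIR10.1 RefSeq gene table, in which 31993 of the 32627 loci were found. The table was used for names and for which genes neighbour each other, and no coordinates are given because the array's annotation build is not stated. Where a locus had several transcript models (3602 loci), the model with the highest mean over the 6 arrays stood for it in the gene lists and the text. Probes of near-identical paralogs may read each other's transcripts. This applies to LHCB1.1, LHCB1.2 and LHCB1.3, the RBCS genes, NRT2.1 and NRT2.2, and CYP71A12 and CYP71A13.

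Light minus dark was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all 37118 models, with a threshold of 0.05. Standard errors (SE) are limma's moderated ones. Gene lists were tested against all other genes with limma's camera, with an inter-gene correlation preset at 0.01, and adjusted over the 26 lists. Each list was also tested by camera with an estimated correlation and by fry. The 26 lists, with 559 members of which 558 were measured (BZIP1 was not on the array), the tests and most other settings tried were fixed before the data were examined. The genes named in the text were chosen by a rule fixed then: the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, up to 4 members per list with the lowest p, and 12 genes always included (HY5, HYH, PHYA, PHYB, CRY1, PHOT1, CHS, FLS1, MYB12, LHCB1.3, RBCS1A and PIN3). Genes outside the rule are named as chosen after their values were seen.

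The fit was tested on simulated data of the same size (37118 models, 3 against 3, 3 runs). It recovered 50.7% of 300 simulated 2-fold changes and 84.3% of 300 simulated 4-fold changes, and 5.81% of its calls were false. Each run changed 200 models, against 2099 called in the data, and the simulated shifts were not held below the top of the scale. The recovery is therefore not that of the real fit. The simulated genes were independent of each other, which real genes are not, so the simulation does not test the preset correlation of camera.

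The replicate numbers in the labels were checked as a possible pairing of dark and light arrays. Correlations of the deviations from the group means between arrays of the same number were 0.01, 0.06 and 0.41, and dark replicate 2 correlated best with light replicate 1 (0.36). The 0.41 was between the replicates numbered 3 and was the highest between groups, so a factor shared by those arrays is not excluded. The main fit did not model such a factor. Because the other same-number correlations were low, the numbers were not used as pairs, and the fit with a replicate block was run as an alternative. Other alternatives were leaving out each array, quantile normalizing again, centring on array medians, filters at the 25th percentile and the median of signal, a signal-dependent and robust variance prior, array weights, the mean of a gene's models, a threshold of 0.01 and an added 2-fold bound. The variance prior with only the trend or only the robust setting, and tests of gene families, were added after seeing the data. These families were groups of genes sharing a symbol prefix, or the genes of an organelle genome, so a group need not be a biological family. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.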

Results

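The data compare the root transcriptome of Arabidopsis plants whose roots grew in light with that of plants whose roots grew in darkness, while the shoots of both were lit. The question is which root transcripts depend on direct illumination of the root. Each group had 3 arrays, each from a separate plate. Array values correlated at a mean Pearson r of 0.992 between arrays of one group and 0.987 between arrays of different groups, across transcript models, which are not independent replicates. Not every pair within a group exceeded the pairs between groups. Light replicate 3 correlated with light replicates 1 and 2 at 0.9885 and 0.9887. Light replicate 1 correlated at 0.9892 with each of dark replicates 1 and 2. The first principal component took 45.5% of the variance and separated the groups, and the second took 24.2% and set light replicate 3 (45.3) apart from light replicates 1 (-37.2) and 2 (-34.8). Dark replicate 3 (27.4) lay on the side of light replicate 3, with dark replicates 1 and 2 at 10.3 and -11.1. Many values lie near the top of the scale, called the ceiling here. In the brightest of 10 equal classes of models the median within-group SD was 0.064 and 0.593% of models passed the test, against 0.539% in the dimmest class. Calls were most frequent at middle signal, with 11.4% and 13.4% of models in classes 4 and 5 counted from the dimmest.

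Light-grown roots had higher levels of many transcripts of the flavonoid and photosystem lists, and lower levels of several iron acquisition transcripts. The largest measured rise was in chalcone isomerase (TT5, also CHI), from 9.88 ± 0.39 in dark-grown to 15.47 ± 0.09 in light-grown roots (mean ± SD, n = 3), a difference of 5.59 on the log2 scale, or 48.2-fold. Flavonol synthase FLS1 (44.1-fold), chalcone synthase (TT4, also CHS; 35.6-fold), flavonoid 3'-hydroxylase TT7 (28.9-fold) and the hydroxycinnamate glucosyltransferase UGT84A1 (28.3-fold) followed, with the early light-induced protein ELIP1 (22.1-fold) and the photosystem II protein PSBS (NPQ4, 22.0-fold). The uncharacterised AT1G56060 (log2 difference 4.76) and the genes AT2G22590 (5.04) and AT5G08050 (4.66) complete the 10 largest measured rises. CHI and CHS in light lie close to the ceiling, so their folds are best read as lower bounds and the order of CHI, FLS1 and CHS is not resolved. PSBS, AT2G22590 and AT5G08050 in dark, and SWEET3, AT3G02100 and AT2G44220 in light, have levels under 7, in the dimmest part of the scale, so their folds and ranks are approximate. The largest falls included the cytochrome P450 genes CYP93D1 (12.8-fold lower in light), CYP76G1 (9.15-fold lower) and CYP712A2 (8.32-fold lower), the hydroxysteroid dehydrogenase HSD4 (7.76-fold lower) and the sugar transporter gene SWEET3 (7.08-fold lower). In a test added after seeing the data, the 240 genes sharing the symbol prefix CYP did not shift as a group. Of these, 11 were higher and 18 lower, with camera adjusted p = 0.928. The group is defined by symbol, so it need not match the P450 family.

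The other 5 of the 10 largest falls were AT3G02100 (-3.34), AT1G73120 (-3.33), AT2G44220 (-2.78), AT1G15540 (-2.73) and AT1G68040 (-2.72). In limma, 2099 of 37118 transcript models differed at adjusted p under 0.05, 1196 higher and 903 lower in light, which is 1066 and 802 genes. In all 2099, the light values lay entirely on one side of the dark values. Of all models, 28.4% had groups that did not overlap, where chance gives 10%. The counts depend on the variance model and on single arrays: with a signal-dependent robust prior 1852 models were higher and 1879 lower, and without any 1 array 607 to 905 were higher and 158 to 473 lower. With models below the 25th percentile of signal removed, 1631 were lower.

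**Figure D1:**
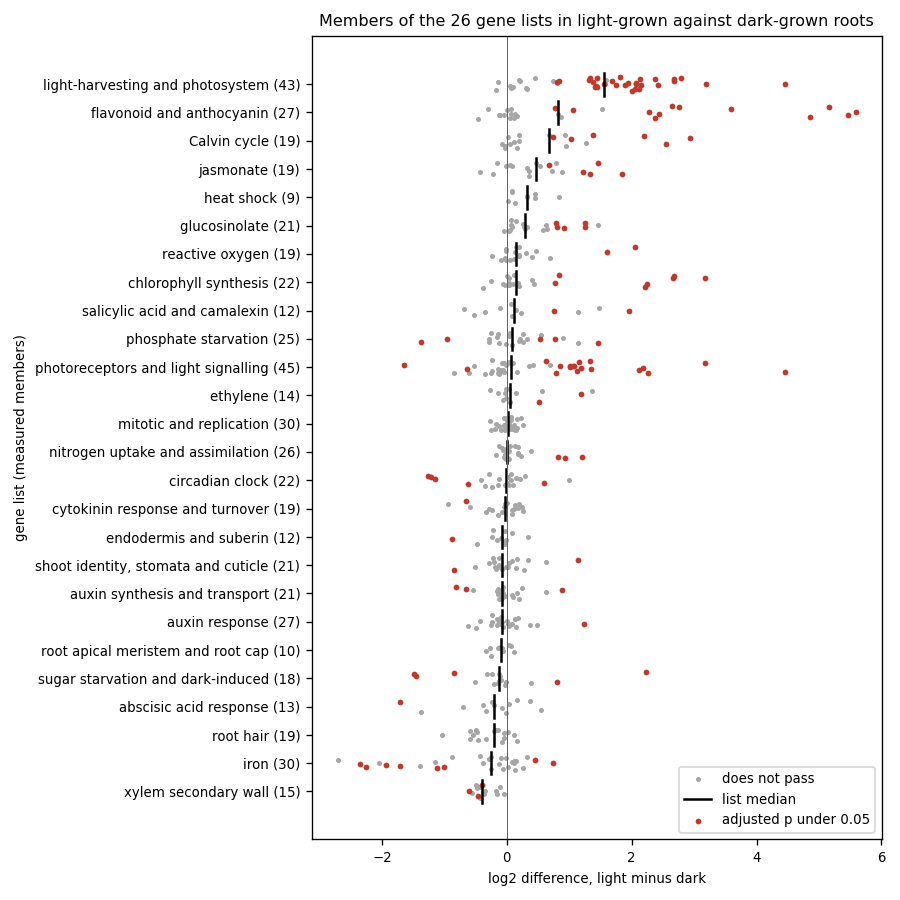
Log2 difference (light minus dark) of each measured member of the 26 gene lists, 1 point per gene, with the number of measured members in parentheses. Red points pass adjusted p under 0.05 and black bars mark list medians, of which the photosystem list's is the highest at 1.55 and the xylem list's the lowest at -0.40.

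Of 27 measured flavonoid and anthocyanin genes, 12 rose, none fell and 15 did not pass the test (13 higher and 1 lower adjusted over the list alone). FLS1 rose by 5.46 (SE 0.17, adjusted p = 0.000623), the chalcone isomerase-like gene CHIL, close to the ceiling in light, by at least 2.43 (SE 0.10, adjusted p = 0.000623) and the flavonol glycosyltransferase gene UGT78D1 by 2.76 (SE 0.11, adjusted p = 0.000623). MYB12, a transcriptional activator of flavonol genes, was at 11.71 ± 0.35 in dark and 14.36 ± 0.18 in light (SD, n = 3), a rise of 2.65 (adjusted p = 0.00257 in limma). DFR and LDOX of the later anthocyanin branch and the anthocyanin regulator PAP1, chosen after their values were seen, did not pass. They differed by 0.06 (SE 0.18), -0.30 (SE 0.30) and 0.13 (SE 0.25), all 3 at levels under 7 in both groups, in the dimmest part of the scale. These 3 do not stand for the whole branch.

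The list median was 0.82 and camera gave adjusted p = 2.88e-11, with adjusted p = 0.122 with an estimated correlation.

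**Figure D2:**
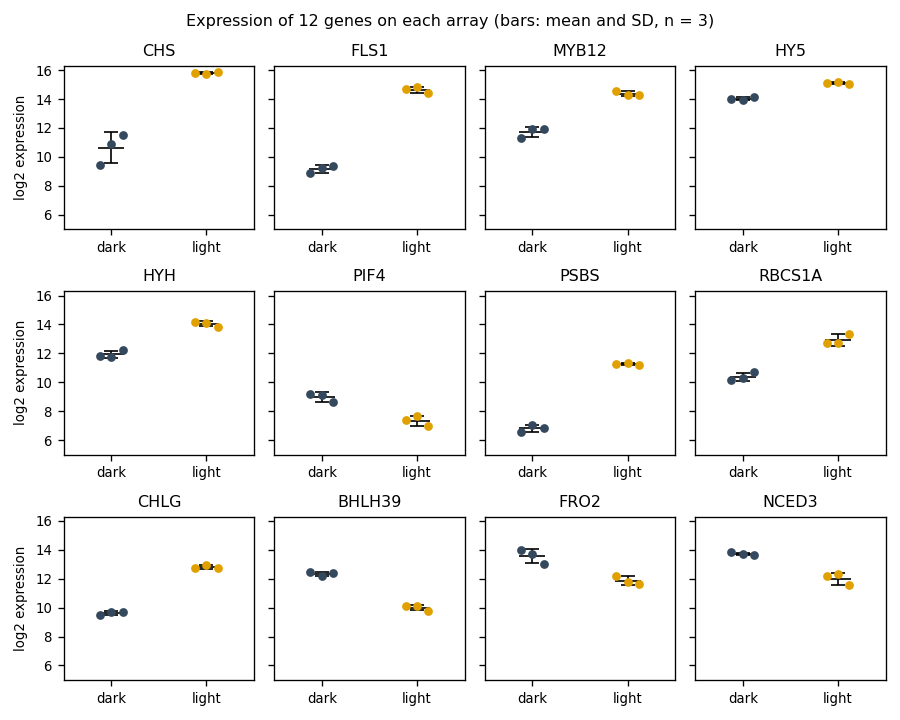
Log2 expression of 12 genes on each of the 6 arrays, dark-grown on the left and light-grown on the right of each panel, with bars for mean and SD (n = 3). The arrays of light-grown and dark-grown roots do not overlap for any of the 12. This follows from the choice of genes that passed limma's test, since no model that passed has overlapping groups. PIF4 and FRO2 were chosen after their values were seen. HY5 differs by 1.07 against 5.46 for FLS1.

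Of 43 nuclear light-harvesting and photosystem genes, 29 rose, none fell and 14 did not pass. Most of those that did not pass encode light-harvesting proteins, among them every LHCB2 and LHCB4 member of the list. PSBS, which acts in the dissipation of excess light, rose from 6.81 ± 0.26 to 11.27 ± 0.08 (SD, n = 3), and the oxygen-evolving complex genes PSBP1 and PSBQ1 rose by 2.68 and 2.37. The antenna gene LHCA2 rose by 1.43, whereas LHCB1.3 differed by 1.57 with an SE of 0.67 and did not pass (adjusted p = 0.256 in limma), its dark arrays spreading by 1.36 (SD). Chlorophyll synthesis and the Calvin cycle had fewer members past the test, and these all rose: 7 of 22 and 6 of 19.

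Chlorophyll synthase CHLG rose 9.02-fold, protochlorophyllide oxidoreductase PORB rose by 2.67 on the log2 scale, the magnesium chelatase subunit gene GUN5 by 2.67 and the cyclase gene CRD1 by 2.24. In the Calvin cycle, the glyceraldehyde-3-phosphate dehydrogenase genes GAPA and GAPB rose 7.66-fold and 4.58-fold, the Rubisco small subunit gene RBCS1A by 2.55 on the log2 scale and Rubisco activase RCA by 1.03. Adjusted over the list alone, 32 photosystem, 8 chlorophyll and 10 Calvin cycle genes rose. The list medians were 1.55, 0.14 and 0.67, and camera gave adjusted p = 4.34e-28, 4.17e-06 and 2.39e-07. With an estimated correlation, adjusted p = 0.0797, 0.0899 and 0.0807, respectively. The low chlorophyll median against its mean of 0.70 reflects a minority of members with large rises. With models below the median signal removed, the chlorophyll and Calvin cycle lists no longer passed camera (adjusted p = 0.0795 and 0.128).

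Of 45 photoreceptor and light signalling genes, 17 rose, 2 fell and 26 did not pass. ELIP1 rose by 4.46 and ELIP2 from 8.89 ± 0.28 to 12.06 ± 0.04 (SD, n = 3), the repressor gene SPA4 rose by 2.27, and the bZIP transcription factor genes HYH and HY5 by 2.11 (SE 0.16) and 1.07 (SE 0.09). The phytochrome genes PHYA and PHYB differed by -0.06 and 0.06, the cryptochrome gene CRY1 by -0.14 and the phototropin gene PHOT1 by -0.24, none past the test. Chosen after their values were seen, CRY3 rose by 2.18 and the phytochrome-interacting factor gene PIF4 and the transcription factor gene LAF1 fell (-1.64 and -0.64).

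The counts adjusted over the list alone were 18 and 5. The list median was 0.06 and its mean 0.49, with camera adjusted p = 0.000467 and adjusted p = 0.331 with an estimated correlation. PHYA is within 1 of the ceiling. Without any 1 array other than light replicate 3, 10 or 11 members rose, and without any 1 array 0 or 1 fell.

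In the clock list, LHY (-1.15), CCA1 (-1.27) and the clock coactivator gene LNK2 (-1.22, SE 0.07) fell, while the evening gene ELF4 rose by 0.60. The fourth gene to fall, RVE8 (-0.63), was chosen after its values were seen. Of 22 clock genes 1 rose, 4 fell and 17 did not pass. Counts adjusted over the list alone were 2 and 6. The list as a whole did not shift (median -0.01, camera adjusted p = 0.250), and without any 1 array 1 or 2 members fell and 0 or 1 rose.

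Some genes of the jasmonate, glucosinolate and salicylic acid and camalexin lists rose, and most members did not pass. In the jasmonate list 5 of 19 rose and none fell, among them the lipoxygenase gene LOX3 (1.85), the repressor genes JAZ5 (1.46) and JAZ9 (0.68) and the defensin PDF1.2 (1.33). In the glucosinolate list 5 of 21 rose and none fell, with the aminotransferase gene BCAT4 at 1.26, the glucosyltransferase gene UGT74C1 at 1.25, the regulator MYB51 at 0.80 and CYP83A1 at 0.79. The camalexin synthesis gene PAD3 rose by 1.96 and the defence regulator PAD4 by 0.75, 2 of 12 in their list, and CYP71A12 differed by 1.15 (SE 0.35) without passing. The fifth members to rise, JAZ10 (1.21) and the glucosinolate synthesis gene MAM1 (0.91), were chosen after their values were seen. Of 19 reactive oxygen genes, 2 rose, the peroxidase genes PRX52 (2.05) and PRX33 (1.60).

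Medians were 0.46 for jasmonate, 0.29 for glucosinolate, 0.12 for salicylic acid and camalexin, and 0.14 for reactive oxygen. Camera gave adjusted p = 2.12e-05, 2.39e-07, 0.0523 and 0.00698 in that order, and with an estimated correlation adjusted p = 0.299, 0.309, 0.449 and 0.156. In those lists 9, 10, 2 and 4 members rose and 1 camalexin-list member fell, adjusted over the list alone. Without any 1 array, 1 to 4 jasmonate, 2 to 5 glucosinolate and 1 reactive oxygen gene rose. No heat shock gene passed limma's test or an unadjusted p under 0.05 (0 of 9, median 0.32, camera adjusted p = 0.0523). HSFA2 differed by 0.83 (SE 0.34) with a dark SD of 0.70.

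Several regulators of iron acquisition fell in light-grown roots. The transcription factor genes BHLH39, BHLH100 and BHLH101 of the iron deficiency response fell, with log2 differences of -2.35 (SE 0.13), -2.25 (SE 0.29) and -1.94 (SE 0.19), and the transporter gene OPT3 fell by 1.12 (SE 0.08). Of 30 iron genes 6 fell and 2 rose. The other 2 that fell were the ferric reductase gene FRO2 (-1.72) and the metal transporter gene IREG2 (-1.01), and the ferritin gene FER4 and the citrate transporter gene FRD3 rose (0.73 and 0.46), all 4 chosen after their values were seen. The list median was -0.26, with camera adjusted p = 0.0126 and adjusted p = 0.445 with an estimated correlation. With p adjusted over the list alone, 10 fell and 4 rose. Without any 1 array 3 to 6 fell and none rose, and with models below the 25th percentile of signal removed the list no longer passed (adjusted p = 0.0530).

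Of the other nutrient lists, a small number of members passed. In phosphate starvation 3 of 25 rose, the ribonuclease gene RNS1 (1.46), the phosphatase genes PAP10 (0.52) and PS2 (0.77), and 2 fell, the transporter genes PHT1;8 (-1.38) and, chosen after its values were seen, PHT1;9 (-0.96). In nitrogen uptake and assimilation 3 of 26 rose, the ferredoxin-dependent glutamate synthase gene GLU1 (1.21) and the nitrate transporter genes NRT2.1 (0.93) and NRT2.2 (0.81), while 15 members lie within 1 of the ceiling. In the sugar starvation and dark-induced list 2 of 18 rose and 3 fell: EXL1 (2.22) and, chosen after its values were seen, the asparagine synthetase gene DIN6 (0.81) rose, and the branched-chain amino acid catabolism genes BCAT2 and IVD (-1.49 and -1.45) and the dark-induced gene DIN1 (-0.85) fell. Camera adjusted p = 0.0977, 0.0977 and 0.0198, with medians of 0.08, 0.01 and -0.12, and for the sugar starvation list adjusted p = 0.331 with an estimated correlation. Adjusted over the list alone, 5 phosphate genes rose and 2 fell, 3 nitrogen genes rose, and 2 sugar starvation genes rose and 5 fell. Without any 1 array 0 to 2 nitrogen genes and 1 to 3 phosphate genes rose and 0 or 1 phosphate gene fell. In those fits 1 or 2 sugar starvation genes rose and 2 or 3 fell. With a replicate block 0 nitrogen genes rose, and 1 sugar starvation gene rose and 0 fell.

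Among hormone lists few members passed. The auxin synthesis genes YUC3 and YUC5 fell (-0.82 and -0.66), the kinase gene PID rose by 0.88, and the auxin transporter gene PIN3 differed by -0.06 (SE 0.08), near the ceiling. The auxin-conjugating enzyme gene GH3.3 rose by 1.23, the cytokinin synthesis gene IPT5 fell by 0.65, the ethylene synthesis genes ACS8 and ACO1 rose by 1.19 and 0.52, and the abscisic acid synthesis gene NCED3 fell by 1.71 (SE 0.21). These are 3 of 21 auxin synthesis and transport genes, 1 of 27 auxin response, 1 of 19 cytokinin, 2 of 14 ethylene and 1 of 13 abscisic acid genes. Medians were -0.07, -0.08, -0.04, 0.04 and -0.20, and camera adjusted p = 0.354, 0.700, 0.623, 0.182 and 0.250. The auxin response list had a negative median and mean while fry's direction was up (adjusted p = 0.780). Adjusted over the list alone, 1 and 2, 1 and 1, 0 and 1, 4 and 0, and 1 and 2 members were higher and lower. Without any 1 array 0 or 1 ethylene and 0 or 1 auxin synthesis and transport genes rose, and 1 or 2 of the latter, 0 or 1 cytokinin and 0 or 1 abscisic acid genes fell. With a replicate block no ethylene or auxin synthesis and transport gene rose.

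Of 15 xylem secondary wall genes, 3 fell, none rose and 12 did not pass: the fasciclin-like gene FLA12 (-0.61), the laccase gene LAC4 (-0.40) and the vessel regulator gene VND7 (-0.47). CASP5 of the Casparian strip fell by 0.88, 1 of 12 endodermis genes. In the root hair list limma called 0 of 19 (7 lower at an unadjusted p under 0.05), with RSL2 at -1.04 (SE 0.27). Limma called 0 of 30 mitotic and replication genes (3 at an unadjusted p under 0.05) and 0 of 10 meristem and root cap genes (2 at an unadjusted p under 0.05), where SCR differed by -0.34 (SE 0.07).

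Medians were -0.40 for xylem, -0.07 for endodermis, -0.21 for root hair, 0.02 for mitotic and -0.09 for meristem genes, and camera adjusted p = 5.36e-06, 0.250, 0.00721, 0.623 and 0.321. With an estimated correlation, adjusted p = 0.328 for xylem and 0.562 for root hair. Adjusted over the list alone 7 xylem, 1 endodermis and 1 meristem gene fell. Without any 1 array, or with a replicate block, no xylem gene passed. The endodermis count was 0 with a replicate block and 0 or 1 without any 1 array. The list of shoot identity, stomata and cuticle genes, which marks tissue that a root harvest could carry over, had 1 of 21 higher (KNAT1, 1.13) and 1 lower (STM, -0.84), the same counts adjusted over the list alone, and a median of -0.07 (camera adjusted p = 0.921). With a replicate block neither direction had a call, and no fit without 1 array called a gene in both.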

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

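Stability was followed for 133 genes: those of the naming rule and some, not all, of those chosen after their values were seen. Of the 88 that passed, 47 kept their call under every alternative fit that included them, and 41 lost it under at least 1. The threshold of 0.01, the 2-fold bound and the trend-only and robust-only priors were not part of this count. A gene removed by a signal filter was not counted as losing its call. None of the 133 genes turned direction while called. Models higher and lower in light numbered 668 and 290 with a replicate block, 1852 and 1879 with a trend and robust variance prior, 1859 and 1808 with the trend alone (chosen after seeing the data), 491 and 115 at a threshold of 0.01, and 676 and 240 with a 2-fold bound. Of the 958 calls with the block, 878 were among the 2099. Lower models numbered 1631 above the 25th percentile of signal and 1596 above the median. Leaving out 1 array gave 607 to 905 higher and 158 to 473 lower, with less data in each fit; only the higher count without light replicate 3 stayed within 1.5 times. Between 12 and 15 lists then shifted, 64 to 83 list members were higher and 8 to 15 lower. List members numbered 64 higher above the median signal, and 14 lower with the block and 48 with the trend and robust prior. With an estimated correlation 0 of the 12 lists passed camera, at adjusted p = 0.0797 (photosystem), 0.0807 (Calvin cycle), 0.0899 (chlorophyll), 0.122 (flavonoid), 0.331 (light signalling), 0.299 (jasmonate), 0.309 (glucosinolate), 0.445 (iron), 0.156 (reactive oxygen), 0.562 (root hair), 0.328 (xylem) and 0.331 (sugar starvation). Above the median signal Calvin cycle (0.128), chlorophyll (0.0795) and iron (0.597) lost their shift, and iron also above the 25th percentile (0.0530). With fry, clock (0.0243) and salicylic acid (0.0172) passed and root hair (0.143) did not. Heat shock passed above the 25th percentile (0.0477), with array weights (0.0238) and with the mean of a gene's models (0.0438), salicylic acid above the 25th percentile (0.0398), and phosphate starvation with array weights (0.0284). Without 1 array, adjusted p ranged from 0.0497 to 0.345 for ethylene, 0.0498 to 0.531 for abscisic acid, 0.00927 to 0.138 for salicylic acid, 0.00533 to 0.531 for phosphate starvation, 0.0151 to 0.446 for nitrogen, 0.00990 to 0.05001 for sugar starvation and 0.00126 to 0.173 for heat shock. The gap between within-group and between-group correlation was 0.00531 over all models, 0.0148 above the 25th percentile and 0.0368 above the median. Apart from fewer genes or arrays, the cause was not tested. For the variance prior, a test bearing on the ceiling is given under the other observations, but it cannot single out the ceiling. Quantile normalizing again and median centring moved nothing, because the values were already normalized, and the pseudocount alternative was not run on log2 values. Transcripts near the ceiling have little room to rise.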

Other observations

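Some glutathione transferases of the tau class (GSTU), which detoxify electrophiles, rose in light-grown roots, and so did some HCF genes. The family and neighbour tests and these genes were chosen after seeing the data. Of 27 GSTU genes 10 rose, 1 fell and the rest did not pass (median 0.15, adjusted p = 0.746 with an estimated correlation), with GSTU12 at 3.07, GSTU3 at 3.01 and GSTU4 at 2.95, and GSTU28 at -0.50. Of 12 HCF genes, several of which act in photosystem assembly, 5 rose and none fell (adjusted p = 0.746 with an estimated correlation), with HCF107 at 3.38 and HCF136 at 1.25. HCF is a shared symbol prefix, so its members need not be related genes. Of 178 groups tested, formed by symbol prefix or organelle genome, 14 passed camera and 0 passed with an estimated correlation.

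Genes that changed lay next to each other more often than shuffled genes did. Of pairs of neighbouring genes, 151 had both members changed in the same direction, against a mean of 54.5 and a highest value of 82 in 10000 shuffles (permutation p = 1e-04, the smallest they can give), and 45 had members changed in opposite directions. Tandem duplicates and probes that read more than 1 paralog were not removed.

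Tests of the other splits of the 6 arrays were fixed before the data were examined; the tests of leaf genes with room below the ceiling and of the second iron array were chosen after the results were seen. Only 10 splits exist, too few for a share under 0.05. The real split called 2099 models and 1 of the 10 splits, the real one, gave as many, with 0 in the highest other. For gene lists the real split gave 12 and the highest other 9. Camera called glucosinolate and root hair in 5 of the 9 other splits, xylem in 6 and the photosystem list in 9. Of the 12 lists, root hair had a smaller p in 2 other splits and iron in 1, and the rest in none. The largest other median exceeded the real one in size for glucosinolate (0.31 against 0.29) and light signalling (0.14 against 0.06). Every other split sets 2 dark and 1 light arrays against 1 dark and 2 light, so it keeps part of any real difference and is not a setting without change.

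The photosystem genes rose on all 3 light arrays: the lowest of their medians against the dark mean was 1.48, which argues against 1 array alone. Leaf tissue carried over into the light-grown harvest could raise them too, and under the test fixed beforehand, 12 leaf-abundant genes outside the photosystems had a median of 0.025 (95% bootstrap range -0.14 to 0.60), below the bound of 0.78; but 5 of the 12 sit near the ceiling, and the 7 with room below it had a median of 0.51 (0.02 to 1.37), a range that includes the bound. The shoot identity, stomata and cuticle list had a median of -0.07. Whether its members would register a small share of leaf tissue was not tested, so this median does not decide the question. Leaf-abundant LHCB2.1, LHCB2.2 and RBCS2B, chosen after their values were seen, differed by 0.44, -0.14 and -0.08 without passing. They come from the photosystem and Calvin cycle lists, in which 29 of 43 and 6 of 19 members rose, so no conclusion is drawn from them. These 3 also lie at the dim end of the scale, where the spread between replicates is larger than near the ceiling. Whether a small share of leaf RNA would show in them was not tested. Leaf carry-over and a response of the root therefore cannot be told apart from these values. In the leaf-abundant set CA1 and HPR1 rose by 1.41 and 1.37, and the photorespiratory gene AGT1 fell (-0.58). The leaf myrosinase gene TGG1 was at -1.38 without passing, and all 4 were chosen after their values were seen. Genes of the plastid genome had a median of 0.083 (0.053 to 0.16) with none of 87 past limma's test, which argues against a matching rise there, though 44 of the 87 lie within 2 of the ceiling. The bootstrap ranges of the leaf-abundant and plastid genes are over genes and do not measure variation between arrays.

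For the fall of iron genes, the test fixed beforehand took the 27 genes without ferritins (median -0.28), which had a median of only -0.09 on light replicate 1, too small by that test's bound for all 3 arrays to share the fall. Because light replicates 2 and 3 were at -0.43 and -0.42, a second test asked whether a single array carries the fall, but its value of -0.42 was known when it was written, so it adds no independent evidence. The list passed camera without each array in turn (adjusted p = 0.00104 to 0.0452), so its call does not need any 1 array, though it is lost with an estimated correlation (0.445). Of the 9 other splits of the arrays, 2 passed camera and 1 had a smaller p than the real split. The largest median in those splits was 0.252 in size, against -0.255 in the real one. A general shift at that signal level is argued against, since the list median of -0.26 lay at percentile 0 of 10000 lists matched on signal (-0.09 to 0.06). That comparison is over genes and does not measure variation between arrays.

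The trend and robust prior gained 1763 calls, and compressed spread near the ceiling is a candidate explanation. Of the gained calls 38.3% were above the upper quartile of signal against 11.7% of the plain fit's calls, 26.6 percentage points more, and their median size was 0.43 against 0.90. Whether these small differences of bright transcripts are biological was not tested.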
